A study of Mus musculus with 6 samples.

How the data were processed

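RNA from 6 samples of mouse P19 cells was measured on 6 Agilent single-colour (Cy3) whole-genome arrays, 1 array for each of 2 lines in each of 3 states. Per the file headers, the scanner output of each array was read by the authors with Agilent Feature Extraction 10.1.1.1, and the column used here, the processed signal, is an intensity: spot brightness after background subtraction and detrending within the array, with no scaling between arrays. The raw spot and local background brightness in the same deposited files served for 1 alternative background correction. The authors also deposited values of their own for each probe, and the unit of this deposited value column is a score. Set against the scanner output, that score equals the log2 signal relative to the array's 75th percentile and to the probe's median over the 6 arrays, with a negative value written as minus the reciprocal of its size and small values left blank; between 99.3% and 99.7% of the listed values matched this reading within 0.01. Of its 41252 probes, 23271 are blank on every array, so these values were not used for tests. The labels do not name the aligner or annotation behind the probes; the array header gives genome build mm9, and no coordinates are given here for that reason.

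Each array held 45018 spots, of which 1639 were controls. Processed signals of spots of the same probe were averaged on the linear scale, before the log2 was taken (245 probes have 10 spots each). Probes were given gene symbols through their RefSeq accession in an annotation of GRCm38. Of 41174 probes, 24844 received a symbol (17178 genes) and 16330 did not; 27 probes had no value on at least 1 array. Signals were expressed as log2 of the processed signal minus the array's 75th percentile (normalized log2 signal). A probe was kept when Feature Extraction called it well above background on at least 2 of the 6 arrays, which left 28485 probes. For a gene with several probes (5955 genes) the probe with the highest mean over the 6 arrays was used; where the other probes of a gene named below differ, their values are given beside it. This left 13381 genes for the tests.

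The model was fitted with limma 3.58.1 in R 4.3.3 (files were read with the data.table package, version 1.17.8), with a term for each state and a term for the line, followed by eBayes and Benjamini-Hochberg adjustment over the 13381 genes at 0.05. The model has 2 residual degrees of freedom per gene and a prior worth 2.05 more. With 1 array per line and state, the spread that the test uses is the variation of the line difference between states, so a gene whose line difference changes with the state has a large error. All tests are two-sided. The p-values therefore set a difference against this variation between states, which mixes effects that depend on the state with noise. Nothing in the labels says that the arrays came from separate cultures, so that noise may be technical. No p-value here measures a spread between replicate cultures. Comparisons of single arrays have no test and are given as values, and counts of genes at least 2-fold or 10-fold apart take genes well above background on both arrays.

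A fold against an array on which a gene was not well above background is a lower bound. It is the signal on the other array over the lowest normalized signal found among probes well above background on the dim array, and is written as at least N-fold; where several arrays are compared, the bound is taken on their mean. Where only some arrays of a group were dim for a gene, its p stays in the counts but no fold is printed for that comparison. Medians of gene lists are also given with such genes at their bound.

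The groups, the tests, the gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. By that rule, symbols of clone or predicted-gene style are not named. For the lines over the 3 states it names up to 10 genes per direction with the largest difference among those past adjusted p 0.05, of the same sign in all 3 states and well above background on all 6 arrays; where fewer pass, genes of the same sign in all states with the largest smallest difference fill the place and are given as values. It adds up to 5 genes per direction, by their bound, that were well above background on all 3 arrays of 1 line and on none of the other. Within a state it names the 5 highest and 5 lowest differences and up to 3 bounds per direction. For each step between states it names the 10 largest changes per direction past adjusted p 0.05 with the same sign in both lines and well above background on all 4 arrays, and up to 5 bounds per direction. In each gene list it names up to 4 members with the largest difference, and it names App and the genes earlier reported to respond to AICD in every comparison. Genes named outside this rule were chosen after their values were seen: some list members beyond the largest 4 of a comparison (Hes1, Hey1, Prrx1, Dcn, Stra6, Pou4f1, Gng3, Nefh, Syn1, Msi1, Psen2, Car9 and Top2a among them), the genes of the whole course from the undifferentiated to the differentiated state, and further genes in the closing part.

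The 24 gene lists cover pluripotency, retinoic acid response, neural progenitors, neurogenic transcription factors, neuron structure and synapse, neurotransmitter systems, glia, mesoderm and muscle, endoderm, mesenchyme and extracellular matrix, neural crest, endothelium and blood, p53 targets and apoptosis, cell cycle, genes earlier reported to respond to AICD, the Notch pathway, the APP family and its processing, imprinted genes, stress and the unfolded protein response, hypoxia and glycolysis, interferon response, targets of Wnt, BMP and Shh, and, as controls, ribosomal proteins and common reference genes. They were tested with camera in limma at its preset correlation between genes, with Benjamini-Hochberg adjustment over the 24 lists. Camera with an estimated correlation and fry were run beside it. With an estimated correlation, camera refers its statistic to the 2 residual degrees of freedom of the model. Few lists can then pass, whatever their correlation, so a lost call does not show that correlation between genes undid it. For single arrays, a list's median was placed among the medians of 10000 random lists of the same size drawn from 20 bins of matched mean expression. Random lists hold unrelated genes, whereas members of a real list may vary together (estimated correlation 0.62 for neuron structure). An extreme percentile is therefore easily reached and is a description of these arrays, not a test.

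The alternatives were median scaling, quantile normalization, no filter on dim probes, a filter on all 6 arrays, a floor at the lowest signal well above background, the mean of a gene's probes, eBayes with an intensity trend and a robust prior, models without the block, every probe tested on its own, a 3-fold threshold and leaving out each array. After the data were seen, 2 more were added: normexp background correction (offset 50) on median spot signals with quantile normalization, in place of a version on mean signals that the files lack, and the 4 arrays of the second slide alone. The undifferentiated pair was hybridised on 1 slide and the other 4 arrays on another. A slide term is absorbed by the state terms for the comparison of the lines, whereas any difference between the undifferentiated and the other states is confounded with the slide.

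The same code was tested on simulated data: in 10 draws, known differences were put into 200 of 13381 genes of noise with the spread of these arrays. Differences between the lines of log2 size 1, 2, 3 and 5 were called for 15.4%, 55.0%, 73.6% and 89.6% of genes, and differences between the differentiated and aggregated states for 0.8%, 50.2%, 66.4% and 85.0%. False calls were 43 of 1211 and 44 of 1056. A list of 20 genes shifted by 1 was found, at an unadjusted camera p under 0.05, in 10 of 10 draws. The simulated genes varied independently, whereas members of the real lists had estimated correlations of up to 0.81 (ribosomal proteins). These draws therefore do not measure how well lists of correlated genes are found. The number of arrays limits the precision of every value.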

Results

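The data describe P19 cells, a mouse embryonal carcinoma line that forms neurons and glia after aggregation with retinoic acid. A line that expresses AICD, the intracellular domain that gamma-secretase releases from the amyloid precursor protein APP, was compared with a line that carries the empty pCDNA vector. Each line was sampled in 3 states: undifferentiated, aggregated (4 days as aggregates with all-trans retinoic acid) and differentiated (2 further days after replating). There was 1 array per line and state, 6 in all, and no replicate within any line and state. Between 62.0% (AICD aggregated) and 65.9% (vector differentiated) of the non-control spots on an array lay well above background, and 0 spots were saturated. The 75th percentile of the processed signal ran from 529 to 878, and replicate spots of a probe within an array had a standard deviation of 0.0679 to 0.0824 on the log2 scale. Across genes, which are not independent replicates, the vector and AICD arrays correlated with Pearson's r of 0.971 in the undifferentiated, 0.970 in the aggregated and 0.964 in the differentiated state. The undifferentiated and differentiated arrays correlated with r of 0.837 in the vector line and 0.895 in the AICD line.

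The comparison of the lines over the 3 states asks which transcripts differ in AICD-expressing cells whatever their state. In limma with the state as a block, 28 genes were higher and 19 lower in the AICD line, 47 of 13381 tested. Plin2, which coats lipid droplets, was higher by 5.21 ± 0.17 (log2 difference ± limma standard error, n = 3 arrays per line; adjusted p = 0.0266). Igf2r, the imprinted receptor that carries Igf2 to lysosomes, was lower by a log2 difference of -5.04 ± 0.27 (adjusted p = 0.0295). Pmaip1, the pro-apoptotic p53 target Noxa, was well above background on the 3 AICD arrays and on none of the vector arrays, at least 13.5-fold higher (adjusted p = 0.0295). Nid1, a nidogen of basement membranes, showed the opposite pattern, at least 63.1-fold lower in the AICD line (adjusted p = 0.0268).

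Of the 47 genes, 16 were well above background on all 6 arrays, 9 of them higher and 7 lower. Beside Plin2, the 9 comprised Gramd1a, a carrier of cholesterol between membranes (4.67 ± 0.23, adjusted p = 0.0295), Ctsc, the lysosomal peptidase cathepsin C (4.01 ± 0.19, adjusted p = 0.0279), and Klhl22, a substrate adaptor of a cullin ubiquitin ligase (3.24 ± 0.19, adjusted p = 0.032). The tetraspanin Tspan6 (2.74 ± 0.19) and the transcription factor Gata2, which acts in blood progenitors and in neurons (2.50 ± 0.15), were also higher, with adjusted p of 0.0383 and 0.032. Smaller positive differences were those of the mitochondrial ATP-Mg carrier Slc25a24 (2.08 ± 0.13), the heme transporter Slc48a1 (1.88 ± 0.13) and Ankrd26 (1.62 ± 0.12). Another probe gave 1.36 for Slc25a24, another gave 0.97 for Slc48a1, and the 5 probes of Ankrd26 ranged from 1.45 to 1.93. Beside Igf2r, the 7 lower genes comprised Tmem141 (-3.83 ± 0.24), the chromodomain gene Cdyl2 (-3.26 ± 0.20), the immunoproteasome subunit Psmb10 (-2.48 ± 0.17) and the galactosyltransferase B4galt4 (-2.41 ± 0.13). The calcium-dependent kinase Camk4 was lower by -2.24 ± 0.13, with -1.53 on a second probe, and Sil1, the nucleotide exchange factor of the chaperone BiP, by -2.23 ± 0.12. The adjusted p of these 6 lay between 0.0295 (B4galt4 and Sil1) and 0.039 (Psmb10).

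Among genes detected on the arrays of 1 line alone, the chemokine receptor-like Ccr1l1 was at least 10.9-fold higher in the AICD line (adjusted p = 0.0295). Slc10a6, a carrier of steroid sulfates, was at least 128-fold lower (adjusted p = 0.0439), and the nucleotidase Ntpcr at least 17.0-fold lower (adjusted p = 0.0266). The same detection pattern without passing the test was seen for Nr2e1, a nuclear receptor of neural stem cells (at least 10.5-fold higher, adjusted p = 0.203), Mettl7a1 (at least 7.51-fold, 0.0581) and Rgcc (at least 6.86-fold, 0.0933). On the lower side it was seen for Rbp4, the plasma retinol carrier (at least 22.2-fold, adjusted p = 0.107), and Slc27a2, an acyl-CoA synthetase (at least 12.9-fold, 0.0605). Large differences of 1 sign in all 3 states that did not pass were those of Ptprt, a receptor tyrosine phosphatase (9.82, 7.60 and 6.84 in the undifferentiated, aggregated and differentiated states, adjusted p = 0.0541), and Slc32a1, the vesicular GABA transporter (-5.41, -3.72 and -3.31, adjusted p = 0.0798). The others were those of the cardiac transcription factor Nkx2-5 (-4.93, -3.90 and -3.29, adjusted p = 0.0567) and Sfxn3 (-3.29, -3.49 and -5.11, adjusted p = 0.0751). All 47 genes had the same sign in the 3 states and a fitted difference of at least 2-fold, and 1673 genes had an unadjusted limma p under 0.05. Sign and size follow largely from the call, since the test takes the variation of the line difference between states as its error. For genes not well above background on every array, the fitted size rests partly on dim signals. With normexp background correction 19 genes were called, with no filter on dim probes 0, and in the within-slide fit to the 4 arrays of the second slide 97, of which 30 were among the 47; the slide of the undifferentiated pair holds 1 array per line and allows no test. The count fell to 0 without any 1 of the aggregated or differentiated arrays and was 97 without either undifferentiated array.

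**Figure D1:**
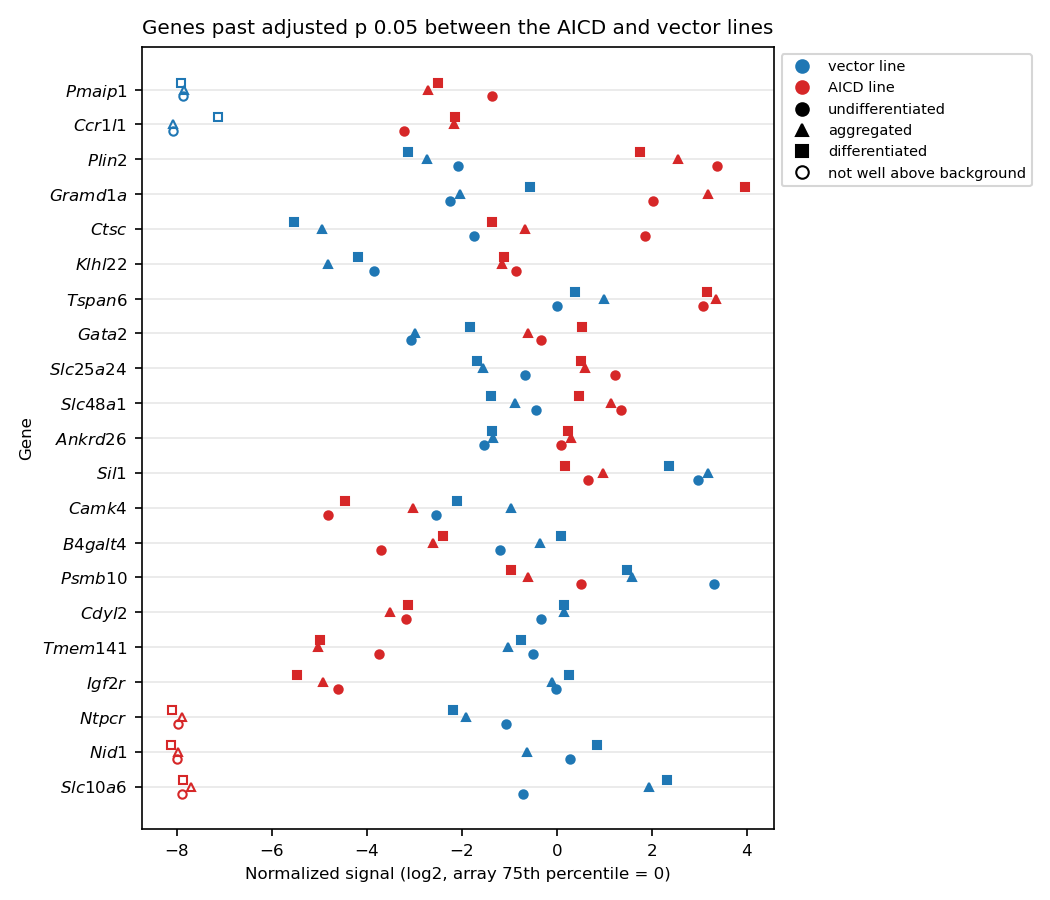
Normalized log2 signal (x axis, relative to each array's 75th percentile) of 21 genes past adjusted p 0.05 between the lines, with colour for the line, marker shape for the state and open symbols for signals not well above background. For Plin2 the 3 AICD arrays lie 5.45, 5.28 and 4.88 above the vector arrays of the same state, and for Igf2r they lie -4.59, -4.82 and -5.72 from them.

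Among the gene lists, 5 of 24 differed between the lines by camera with its preset correlation, and with an estimated correlation, as with fry, 0 did. In camera with an estimated correlation, the 2 residual degrees of freedom alone leave little room for a call. The glial list had an estimated correlation of -0.05, yet its unadjusted camera p was 0.00142 at the preset and 0.0795 with the estimate. In the steps between states, described further on, 0 list calls held with an estimated correlation either, and fry called 12 lists on aggregation and 3 after replating. Mesenchyme and extracellular matrix genes were lower in the AICD line (adjusted p = 0.0141; adjusted p = 0.902 with an estimated correlation): 20 of 26 measured members had negative differences, Ccn2 (connective tissue growth factor) was called higher, and 0 were called lower. Adjusted over the list alone, 1 member was higher and 3 lower; the median was -0.57, or -0.62 with genes at their bound. The states differed here: the list had a median of 0.18 in the undifferentiated state, with 14 of 26 members higher, 7 at least 2-fold higher and 4 at least 2-fold lower, -0.72 in the aggregated and -1.97 in the differentiated state. Among its lowest line estimates were those of Snai2, a regulator of epithelial to mesenchymal transition (-2.77, -4.18 and -5.28 in the 3 states), Thy1 (-2.94 undifferentiated, then at least 11.5-fold and 39.2-fold lower) and Pdgfrb, the PDGF receptor of pericytes and fibroblasts (-0.67, then at least 32.6-fold and 104-fold lower). Interferon response genes were lower as a set (adjusted p = 0.0398; adjusted p = 0.902 with an estimated correlation), with 10 of 14 negative, 0 called over all genes and 1 higher and 4 lower adjusted over the list alone; the median was -0.55, or -0.32 with genes at their bound. Examples are Bst2 (-2.17) and the immunoproteasome subunit Psmb9 (-1.24), while B2m had 0.70.

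Glial genes were higher as a set (adjusted p = 0.0171; adjusted p = 0.902 with an estimated correlation), with 9 of 10 positive, 0 called over all genes or adjusted over the list alone, and a median of 0.40; Aldh1l1 had 0.79 and Slc1a3, the astrocyte glutamate transporter, 0.81. Cell cycle genes were higher (adjusted p = 0.0251; adjusted p = 0.902 with an estimated correlation), with 23 of 32 positive, 0 called over all genes, 1 higher adjusted over the list alone and a median of 0.17. The largest members were inhibitors of cell division: Cdkn2a (5.20 undifferentiated, then at least 28.0-fold and 12.5-fold higher) and Cdkn2b (1.77, adjusted p = 0.414). Pluripotency genes were higher (adjusted p = 0.0398; adjusted p = 0.902 with an estimated correlation), with 15 of 22 positive and 0 called over all genes or adjusted over the list alone; the median was 0.30 (0.12 with genes at their bound) and the mean 0.77. In the undifferentiated, aggregated and differentiated states the medians were 0.30, 0.39 and 0.27 for glia, 0.13, 0.03 and 0.35 for the cell cycle, -0.92, -0.36 and -0.26 for interferon response (-0.23, -0.13 and -0.10 with normexp correction) and 0.01, 0.36 and 0.90 for pluripotency. The aggregated cell cycle median was -0.06 with normexp correction. The calls of the interferon and pluripotency lists ended with normexp correction (adjusted p = 0.253 for both).

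The other 19 lists did not pass. Median differences were 0.29 for neural progenitors, where the interneuron progenitor factor Dbx1 was called higher (at least 5.45-fold, then 5.84 and 4.81; adjusted p = 0.0415), 0.17 for neurogenic transcription factors, 0.07 for neuron structure and synapse, -0.08 for neurotransmitter systems and -0.02 for retinoic acid response. They were 0.11 for mesoderm and muscle, 0.00 for endoderm (-0.01 with quantile normalization), -0.19 for neural crest, and -0.04 for endothelium and blood (0.01 with normexp correction), where Gata2 was called. The imprinted genes had a median of 0.16 and a mean of -0.12, with Igf2r called lower, and the p53 and apoptosis list had a median of -0.03 (0.00 with quantile normalization) and a mean of 0.08, with Pmaip1 called higher and Casp8 at least 5.01-fold lower (adjusted p = 0.0798). The Notch list had a median of 0.08 and a mean of -0.63 with a downward camera direction. The APP family had a median of -0.09 and a mean of 0.01, stress genes 0.12, hypoxia and glycolysis 0.04 (-0.02 with normexp correction), and the Wnt, BMP and Shh targets 0.03 with a mean of -0.19 (-0.10 with normexp correction). The control lists had medians of 0.05 (ribosomal proteins) and 0.11 (reference genes). Adjusted over the list alone, 4 retinoic acid response, 1 neuron structure, 1 neural crest and 2 Notch members were lower, 2 neural progenitor and 3 endoderm members higher, 3 neurotransmitter members higher and 1 lower, and 2 mesoderm members higher and 1 lower. The p53 list then held 1 higher and 1 lower member, the reference genes 1 higher and 2 lower, endothelium and blood 1 higher and the imprinted genes 1 lower.

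The list of genes earlier reported to respond to AICD, together with App, asks whether transcripts linked to AICD before differed here. Of 19 measured members 0 were called over all genes by limma, 1 was higher adjusted over the list alone, and the median was 0.01 with a mean of 0.11 and a downward camera direction. Egfr, the epidermal growth factor receptor, had the differences 1.85, 1.15 and 1.28 in the undifferentiated, aggregated and differentiated states (adjusted p = 0.102). App itself had 0.25, -0.49 and -0.82 (adjusted p = 0.645); where its probe lies relative to the transgene is not given in the sources used here, so this value says nothing of transgene expression. Slc17a6, the vesicular glutamate transporter of many neurons, had -1.65 in the undifferentiated state, was at least 31.1-fold higher in the aggregated state and had -0.37 in the differentiated state. Mme (neprilysin) had 1.34 in the undifferentiated and -0.10 in the differentiated state and was not well above background on the aggregated AICD array. In the order of the states, Cd82 had 1.71, -0.06 and -0.61, Igfbp3 0.65, -0.85 and -0.88, and Ptch1 -0.44, 0.48 and 1.60. Aqp1 was not well above background on either undifferentiated array, had 0.07 in the aggregated state and was at least 2.67-fold lower in the differentiated state. The other members had line estimates between -0.15 (Gsk3b) and 0.11 (Tpm1): Bace1 -0.14, Cyp46a1 -0.13, Apbb1 -0.12, Kat5 -0.08, Acta2 -0.06, Tagln 0.01, Trp53 0.02, Lrp1 0.05 and Stub1 0.06.

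Within the undifferentiated state, the comparison of the 2 arrays asks what differed before retinoic acid was given. At least 2-fold apart were 1044 of 12555 genes detected on both arrays, 528 higher and 516 lower in AICD cells, and 71 differed at least 10-fold (36 higher, 35 lower). Higher were Ptprt (9.82), the Ras activator Rasgrp3 (6.66), the chemokine receptor Ackr3 (6.61), the potassium channel subunit Kcns3 (6.57) and Ccn2 (6.47). The alkylation repair enzyme Alkbh3 was at least 70.1-fold, Aldh1a7 at least 47.5-fold and Tbx15 at least 37.6-fold higher. Lower were Gc, the vitamin D binding protein (-7.35), the collagen gene Col8a2 (-6.71), the synaptonemal complex gene Syce2 (-6.61), the hormone gene Trh (-6.42) and Ttc30a1 (-5.63). Rbp4 was at least 111-fold, Nid1 at least 66.5-fold and the splicing factor gene Zrsr1 at least 41.7-fold lower. The median of the pluripotency list was 0.01 (-0.00 with normexp correction), with Pou5f1 at 0.11 and Gdf3 at 0.74. The interferon list had -0.92 (-0.61 with genes at their bound, -0.23 with normexp correction), below all random lists, with Bst2 at -4.67, and the endoderm list 0.48 (percentile 99.99 among random lists; 0.29 with normexp correction). Mesenchyme genes had 0.18 (percentile 99.1), with Col3a1, a fibrillar collagen gene, at 2.03.

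Within the aggregated state, the comparison asks how the lines differed at the end of retinoic acid treatment. At least 2-fold apart were 879 of 11990 genes, 505 higher and 374 lower in AICD cells, with 33 and 24 at least 10-fold apart. Among pluripotency genes, Pou5f1, which encodes Oct4, was higher by 5.59 (normalized log2 signal 3.19 against -2.40), the TGF-beta family gene Gdf3 by 5.79, Nr0b1 by 4.90 and the Nodal antagonist gene Lefty1 by 4.12. The median of this list was 0.36, or 0.33 with genes at their bound (percentile 99.9), and 0.14 with normexp correction, and 7 members were at least 2-fold higher and 1 lower. Ptprt (7.60), Dbx1 (5.84) and Ccn2 (5.77) were also higher, and Alkbh3 was at least 79.5-fold, the carboxypeptidase gene Cpb1 at least 66.5-fold and Nr2e1 at least 63.7-fold higher. Neuron structure genes had a median of 0.78 (percentile 100), with 31 of 35 members higher, among them Syt4 (at least 3.37-fold), Gap43 (1.82) and Syt1 (1.73). The mesoderm list had 0.91 (percentile 100), with 8 of 18 members at least 2-fold higher and 4 at least 2-fold lower, or 0.40 with genes at their bound and 0.31 with normexp correction.

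On the lower side in the aggregated state, the Notch target Hes5 was at least 3041-fold lower in AICD cells, Slc10a6 at least 207-fold and the BMP family gene Gdf10 at least 75.6-fold. The Notch regulator Dtx1 was at least 74.4-fold lower and the Notch target Hey2 had -2.58, while Hes1 had -0.08 and Hey1 1.37. Of 6 Notch targets measured beside Hes5, 3 were lower. Syce2 (-5.14), Col3a1 (-4.85), Igf2r (-4.82), the homeobox gene Msx1 (-4.74) and the lactate carrier Slc16a3 (-4.73) had the lowest differences among genes detected on both arrays. Mesenchyme genes had a median of -0.72 (below all random lists; -0.28 with normexp correction), with 22 of 26 members lower, including Pdgfrb (at least 32.6-fold), Snai2 (-4.18), Prrx1 (-3.04) and Col1a1 (-2.70). Hypoxia and glycolysis genes had -0.56, with 16 of 18 lower, and the retinoic acid response -0.46.

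Within the differentiated state, the comparison asks how the lines differed after replating. At least 2-fold apart were 1053 of 12282 genes, 567 higher and 486 lower in AICD cells, with 43 and 40 at least 10-fold apart. The pluripotency list had a median of 0.90 (0.80 with genes at their bound, percentile 100; 0.45 with normexp correction), with 10 members at least 2-fold higher and 1 lower: Gdf3 had 4.37, Nr0b1 4.30, Sall4 3.98 and Pou5f1 3.88. Ptprt (6.84), the neuronal gene Tagln3 (6.31), Alkbh3 (5.44), Slc35d3 (5.28) and the homeobox gene Nkx6-2 (5.25) were highest, and the transcription factor gene Sp8 was at least 71.7-fold, Cpb1 at least 52.9-fold and Ccn2 at least 40.5-fold higher. Mesenchyme genes had a median of -1.97 (-1.84 with genes at their bound, below all random lists), with 16 of 26 at least 2-fold lower and 2 higher: Col3a1 had -7.86, Dcn -4.67, Col1a1 was at least 68.2-fold and Lum at least 41.4-fold lower. Hes5 had -11.28, and Dtx1 was at least 496-fold, Slc10a6 at least 304-fold and Syt13 at least 146-fold lower; a second probe of Syt13 had a line estimate of -0.41. Zrsr1 (-6.14), Igf2r (-5.72) and Vcam1 (-5.33), a cell adhesion gene, were also among the lowest. Neuron structure genes had a median of -0.40, with 31 of 35 members lower, and cell cycle genes 0.35, with 27 of 32 higher. With normexp correction the 2-fold counts were 593, 482 and 684 in the undifferentiated, aggregated and differentiated states.

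**Figure D2:**
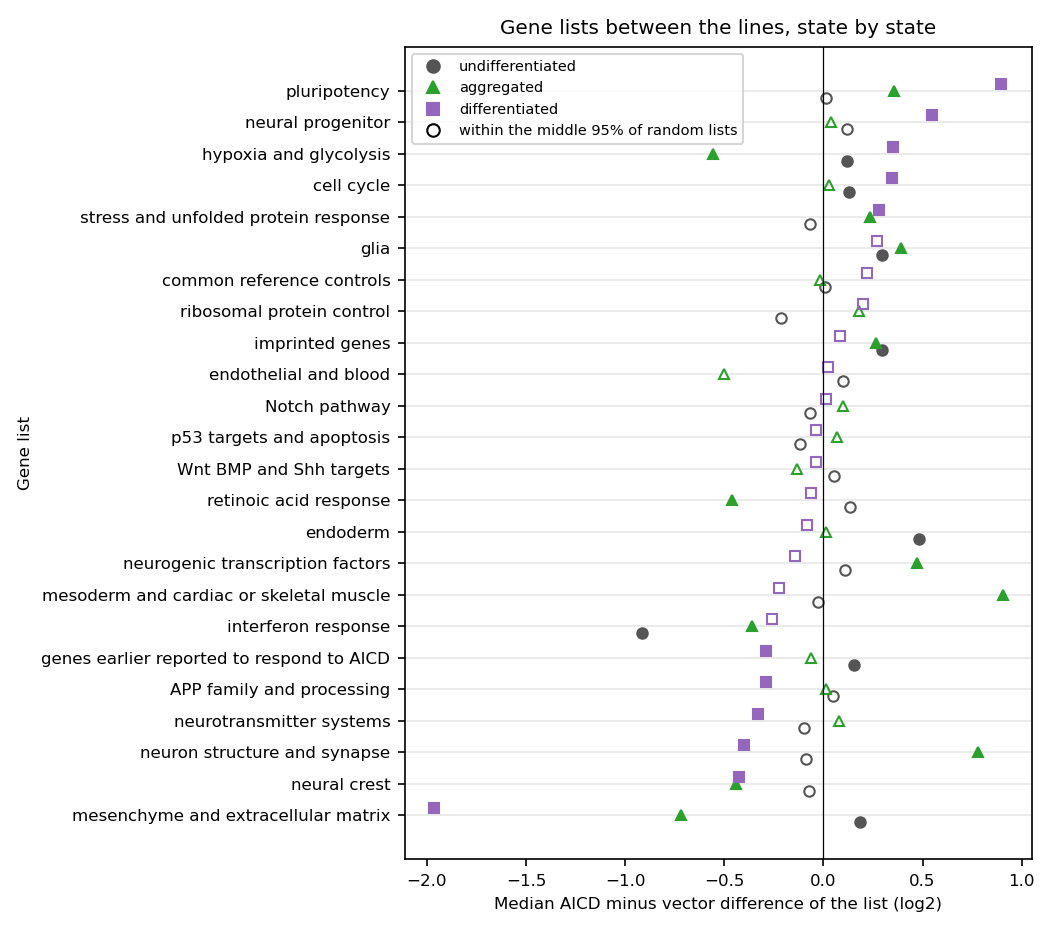
Median AICD minus vector difference (log2, x axis) of each of the 24 gene lists, 1 symbol per state, with open symbols where the median lies within the middle 95% of random lists. The random lists hold unrelated genes, so a filled symbol marks no test. Mesenchyme medians run from 0.18 over -0.72 to -1.97 and pluripotency medians from 0.01 over 0.36 to 0.90.

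**Figure D3:**
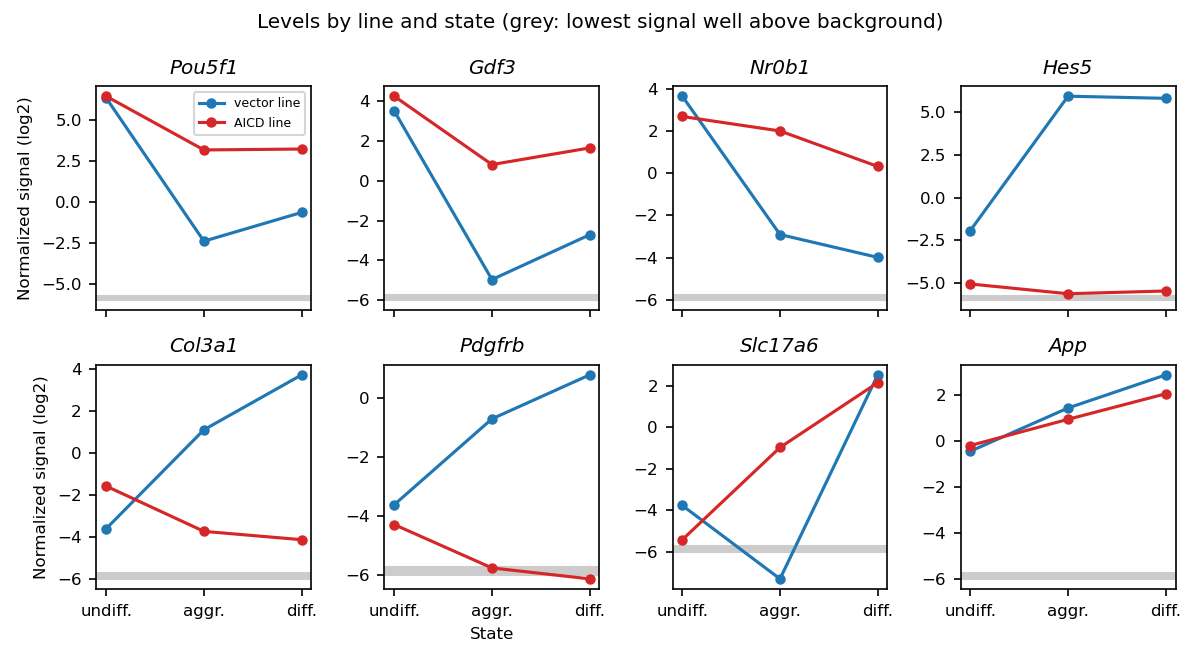
Normalized log2 signal (y axis) of Pou5f1, Gdf3, Nr0b1, Hes5, Col3a1, Pdgfrb, Slc17a6 and App in the 3 states (x axis), 1 line per cell line, with a grey band at the lowest signals well above background. Pou5f1 lies at 6.37 and 6.48 in the undifferentiated vector and AICD arrays and at -2.40 and 3.19 in the aggregated ones.

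How far the line difference was shared between states was measured across 13381 genes, which are not independent replicates. The AICD minus vector differences of the aggregated and differentiated states correlated with Pearson's r of 0.624 (Spearman's rho 0.349), those of the undifferentiated and aggregated states with 0.435 (0.266), and those of the undifferentiated and differentiated states with 0.369 (0.157). Genes 2-fold apart in the same direction in both states of a pair numbered 387, 263 and 259, and those in opposite directions 21, 39 and 64. Of 11481 genes detected on all 6 arrays, 82 were at least 2-fold higher and 76 at least 2-fold lower in all 3 states.

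The step from the undifferentiated to the aggregated state asks which genes respond to aggregation with retinoic acid in both lines. In limma with the line as a block, 1907 genes rose and 3727 fell, 5634 of 13381 (7414 with unadjusted p under 0.05). Hox genes were among those that rose: Hoxb2 was at least 1477-fold, Hoxb5 at least 1352-fold, Hoxb8 at least 1079-fold, Hoxa5 at least 391-fold and Hoxa2 at least 253-fold higher. Dcx, the microtubule protein of migrating neurons, rose by 7.45 ± 0.37 (n = 2 arrays per state; adjusted p = 0.00739). Pou5f1 fell by 6.03 on the log2 scale (standard error 1.40, adjusted p = 0.0363), with -8.77 in the vector line and -3.29 in the AICD line.

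Other genes that rose were Zfp503 (8.75 ± 0.33, adjusted p = 0.00668), Hoxb7 (8.28 ± 0.69), Emid1 (7.06 ± 0.40), the RNA-binding gene Celf3 (7.03 ± 0.53), the granin gene Chgb (6.87 ± 0.30), Hoxb3 (6.71 ± 0.29), Fabp7 of radial glia (6.69 ± 0.35) and Hoxb9 (6.24 ± 0.73). Their adjusted p went up to 0.0135. A second probe gave 11.59 for Hoxb3, 3.74 for Hoxb8 and 6.40 for Dcx. Genes that fell were the ectoenzyme gene Enpp3 (-6.73 ± 1.03, adjusted p = 0.0181), the Nodal co-receptor genes Cfc1 (-6.69 ± 0.43, 0.00861) and Tdgf1 (-5.31 ± 0.26, 0.00739), the let-7 inhibitor Lin28a (-6.21 ± 0.96, 0.0183) and Gdf3 (-5.96 ± 1.30, 0.0322). Calcr (-5.68), Enpp2 (-5.61), the zinc carrier Slc39a8 (-5.38) and the histamine receptor gene Hrh1 (-5.29) fell as well; a second probe of Calcr gave -4.17. Trap1a was at least 410.0-fold, Il20ra at least 144-fold, Cyp2b23 at least 38.8-fold, Mmp25 at least 29.9-fold and the germline gene Tex19.1 at least 27.5-fold lower.

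By list, the retinoic acid response rose (camera adjusted p = 1.15e-14; adjusted p = 0.274 with an estimated correlation): 21 of 25 members rose, Stra6, the cellular receptor for the retinol carrier, fell (-1.67), and 3 did not pass, with 22 higher and 1 lower adjusted over the list alone and a median of 5.41. The retinoic acid hydroxylase gene Cyp26a1 (5.39) and the receptor gene Rarb (5.39) rose. Neurogenic transcription factors rose (adjusted p = 1.46e-12; adjusted p = 0.274 with an estimated correlation), 19 of 26, while Pou4f1 fell (-1.38). Adjusted over the list alone 22 rose and 1 fell, and the median was 3.88, or 3.54 with genes at their bound. Nhlh1 was at least 124-fold and Myt1 at least 90.0-fold higher. Neuron structure genes rose (adjusted p = 1.87e-08; adjusted p = 0.606 with an estimated correlation), 21 of 35, with Mapt at 5.49 and Map2 at 4.72, while Gng3 (-2.24), Nefh (-1.93) and Syn1 (-0.91) fell. Adjusted over the list alone 23 rose and 3 fell, and the median was 1.76, or 1.32 with genes at their bound. Neural progenitor genes rose (adjusted p = 1.64e-05; adjusted p = 0.462 with an estimated correlation), 11 of 21, 14 adjusted over the list alone, with Pax3 at least 110-fold higher and a list median of 2.58; Msi1 (-1.09) and Nkx6-2 (-4.66) fell, the same 2 by either adjustment.

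Pluripotency genes fell (camera adjusted p = 0.00191; adjusted p = 0.606 with an estimated correlation): 13 of 22 over all genes and 14 adjusted over the list alone, with a median of -2.87, or -2.05 with genes at their bound. Notch pathway genes rose (adjusted p = 0.00872; adjusted p = 0.464 with an estimated correlation), 7 of 23 with 2 lower and a median of 0.48; Mfng (4.10) and Nrarp (3.61) rose and Psen2 fell (-1.39). Hypoxia and glycolysis genes rose (adjusted p = 0.0186; adjusted p = 0.663 with an estimated correlation), 6 of 18 with 2 lower and a median of 0.42; Ndrg1 (5.15) and Vegfa (2.26) rose and Car9 fell (-1.21). Neurotransmitter genes went both ways, 8 of 26 higher and 7 lower, 9 and 7 adjusted over the list alone, with a median of 0.79 (camera adjusted p = 0.045, upward; adjusted p = 0.606 with an estimated correlation); this call ended with median scaling (adjusted p = 0.0521). The median steps in the vector and AICD lines, which were not tested against each other, were -3.31 and -1.84 for pluripotency, 6.22 and 5.25 for retinoic acid response, 3.77 and 3.93 for neurogenic factors, and 1.39 and 2.05 for neuron structure. They were 2.82 and 1.38 for neural progenitors, 0.85 and 0.30 for Notch, and 0.14 and 1.49 for neurotransmitter genes. For hypoxia and glycolysis they were 0.86 and 0.16, where 10 of 18 members rose from the undifferentiated to the aggregated state within the AICD line. For Notch and hypoxia the counts adjusted over the list alone were also 7 and 2, and 6 and 2. App rose by 1.51 (adjusted p = 0.0286). Of the genes earlier reported to respond to AICD, 5 rose and 6 fell, with a median of 0.14, a mean of -0.23 and an upward camera direction; Cd82 rose (3.14) and Igfbp3 fell (-3.07). The ribosomal list had -0.38, and 0.02 with quantile normalization or normexp correction.

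The median of all genes was -0.31 in this step and -0.12 with quantile normalization, and rising genes made up 33.8% of the calls, 44.4% with quantile normalization (2141 rose, 2684 fell) and 46.0% with normexp correction (2269 rose, 2662 fell). The undifferentiated arrays were on another slide than the rest, so slide and state cannot be told apart here, and the count was 0 without either aggregated array, 1082 without the undifferentiated vector array and 3711 without the undifferentiated AICD array.

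The step from the aggregated to the differentiated state, which lies within the second slide, asks what changed after replating. In limma 0 genes passed adjusted p 0.05, with 4341 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0535. With eBayes with an intensity trend and a robust prior 849 genes were called, 411 higher and 438 lower, and genes detected on all 6 arrays tested alone gave 733. As sets, neuron structure genes were higher (camera adjusted p = 9.86e-14; adjusted p = 0.575 with an estimated correlation), with a median of 2.05 and 31 of 35 higher and 1 lower adjusted over the list alone. Cell cycle genes were lower (adjusted p = 2.26e-08; adjusted p = 0.575 with an estimated correlation), with a median of -0.93 and 26 of 32 lower adjusted over the list alone. Hypoxia and glycolysis genes were lower (adjusted p = 6.57e-08; adjusted p = 0.575 with an estimated correlation), with a median of -2.61 and 14 of 18 lower adjusted over the list alone.

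Members of these lists are given as values. Among neuron structure genes Mapk10 had 3.25 and Mapt 2.95, and Syn1, a synaptic vesicle gene, -0.63. Among cell cycle genes Ccnd2 had -2.43, Ccnd3 -1.80 and Top2a, a topoisomerase of dividing cells, -1.27. Pdk1, which restrains pyruvate oxidation, had -5.13, Bhlhe40 -4.09, Ndrg1 -3.99 and lactate dehydrogenase gene Ldha -3.54. The retinoic acid response was lower (adjusted p = 1.05e-05; adjusted p = 0.564 with an estimated correlation), with a median of -1.22, or -1.16 with genes at their bound, and 16 of 25 lower adjusted over the list alone. The retinaldehyde reductase gene Dhrs3 had -7.74, Cyp26b1 -7.51, Cyp26a1 -4.69 and Rarb -4.47. Neurotransmitter genes were higher (adjusted p = 2.89e-05; adjusted p = 0.564 with an estimated correlation), with a median of 1.22 and 12 of 26 higher and 1 lower adjusted over the list alone; the AMPA receptor gene Gria2 had 4.48. Wnt, BMP and Shh targets were lower (adjusted p = 0.0185; adjusted p = 0.575 with an estimated correlation), with a median of -1.05 and 1 higher and 2 lower of 23 adjusted over the list alone; Wnt1 had -4.36, and the call ended with median scaling (adjusted p = 0.0942). Ribosomal protein genes were lower (adjusted p = 1.26e-06; adjusted p = 0.646 with an estimated correlation), with a median of -0.89 and 14 of 20 lower adjusted over the list alone; this call ended with quantile normalization (adjusted p = 0.113). The median step of the neuron structure list was 2.60 in the vector line and 1.26 in the AICD line, that of the hypoxia list -3.06 and -1.78, and that of the cell cycle list -1.18 and -0.75. They were -1.21 and -1.25 for retinoic acid response, -1.40 and -0.62 for the Wnt, BMP and Shh targets, and -0.99 and -0.81 for ribosomal proteins. At least 2-fold higher were 17 and 15 of the 26 neurotransmitter genes. These differences between the lines were not tested.

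Single genes detected in 1 of these states only were Agtr2, an angiotensin receptor gene (at least 11.7-fold higher in the differentiated state, adjusted p = 0.0535), Dlx1, a homeobox gene of GABAergic neurons (at least 14.8-fold, 0.105), Spry4 (at least 12.6-fold, 0.0675), Gpr22 (at least 9.71-fold) and Car10 (at least 9.67-fold). On the lower side were Fcgrt, the neonatal Fc receptor (at least 37.1-fold, adjusted p = 0.0675), the mesoderm homeobox gene Meox1 (at least 13.3-fold, 0.0661), the crystallin gene Cryge (at least 9.67-fold, 0.0535), the caudal homeobox gene Cdx2 (at least 9.27-fold, 0.0684) and Clec1b (at least 7.93-fold). App had 1.27 (adjusted p = 0.0915), and of the genes earlier reported to respond to AICD 0 passed by limma over all genes or adjusted over the list alone, with a median of -0.12 and a mean of 0.41. In this step the median and the mean also had opposite signs for the mesoderm, endoderm, neural crest and p53 lists, and the mesenchyme list had a median of 0.16, a downward camera direction and -0.01 with median scaling. The median of all genes was -0.08, and -0.25 with median scaling.

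**Figure D4:**
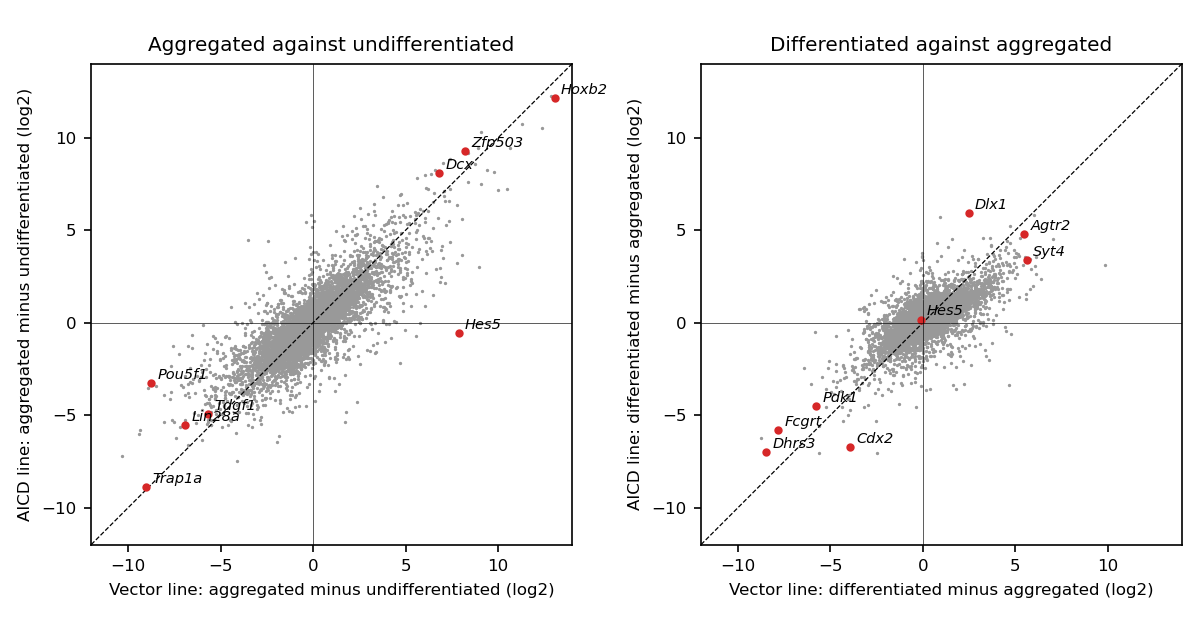
Change of each gene (log2) in the vector line (x axis) and in the AICD line (y axis), for the step to the aggregated state (left) and to the differentiated state (right); each point is a gene, red points are labelled genes, some of them not well above background on every array, and the dashed line marks equal change. The least-squares slope of AICD on vector changes is 0.737 on the left and 0.543 on the right. Such a slope also falls with scatter between the lines (Pearson's r 0.830 and 0.739), so it does not measure response size alone.

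Whether the lines passed through these steps alike was described without a test. At least 2-fold changes on aggregation were seen for 4096 of 12076 genes in the vector line (349 at least 10-fold) and 3316 of 11869 in the AICD line (239 at least 10-fold). After replating they were seen for 2744 of 12210 genes in the vector line and 1350 of 12064 in the AICD line, with 163 and 49 at least 10-fold. Across genes the changes of both lines correlated with Pearson's r of 0.830 on aggregation and 0.739 after replating. Hes5 belongs to the genes with unlike courses: its aggregated signal was well above background in the vector line alone, and its fitted change on aggregation did not pass (adjusted p = 0.265).

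The comparison of the differentiated with the undifferentiated state spans the whole course. In limma 2691 genes rose and 5524 fell, 8215 in all (8996 with unadjusted p under 0.05), and the median of all genes was -0.44, or -0.24 with quantile normalization, where 3060 genes rose and 4533 fell. Dcx (9.51), Chgb (8.98), Celf3 (8.88) and Fabp7 (7.50) rose, and Cfc1 (-7.13) and Pou5f1 (-5.12, adjusted p = 0.0374) fell. Slide and state cannot be told apart here either, and the count was 879 without the differentiated vector array, where the majority turned (512 rose, 367 fell), and 4509 without the undifferentiated vector array.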

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

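The results in this part were picked out after they were seen, by rules on direction and on the random lists, and none of the differences between states or lines below was tested, apart from the count of probes in the last sentence. The neuron structure list had a median AICD minus vector difference of 0.78 in the aggregated state and -0.40 in the differentiated state (35 genes). The mesenchyme and extracellular matrix list had 0.18 in the undifferentiated, -0.72 in the aggregated (-0.28 with normexp correction) and -1.97 in the differentiated state (26 genes). Col3a1, a member of it, had 2.03, -4.85 and -7.86 in the same order. On replating, the median of this list was 0.54 in the vector line and -0.46 in the AICD line. The hypoxia and glycolysis list had 0.12, -0.56 and 0.35 in the undifferentiated, aggregated and differentiated states (18 genes). The genes earlier reported to respond to AICD had a median of 0.15 in the undifferentiated and -0.29 in the differentiated state (19 genes). Hoxb7 had 1.43 in the undifferentiated and -1.30 in the differentiated state. When every probe was tested on its own, 77 probes differed between the lines, of which 21 have no gene name and were not analysed further here.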

How the results depend on the processing

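After the data were seen, 2 alternatives were chosen, the normexp correction on median signals and the 4 arrays of the second slide; all others were fixed before the data were examined. The 47 genes that differ between the lines became 19 with normexp (16 shared), 0 with no filter on dim probes, 16 without the state block, 77 with every probe tested on its own and 97 on the second slide (30 shared). All 47 kept their direction wherever they were measured, which their selection for large and steady differences makes likely beforehand. Leaving out 1 array gave 0 to 97, with 97 without either undifferentiated array and 0 without any other array; with 1 array left in a state, that state adds nothing to the line difference. The 5 lists became 3 with normexp, 1 with no filter, 2 with the filter on all 6 arrays, 3 with the floor, 2 on the second slide, 0 with an estimated correlation and 0 with fry, and 2 to 4 without 1 array. The step to the aggregated state gave 5634 genes, 12620 probes when each was tested on its own, and 0 to 4185 without 1 array, with 0 without either aggregated array; its 8 lists became 0 with an estimated correlation and 8 to 10 without 1 array. The step to the differentiated state gave 0 genes, 733 with the filter on all 6 arrays and 23 with the floor. It gave 849 with a trend and robust prior, 20 without the line block and 766 probes on their own. Of its 7 lists 0 held with an estimated correlation, where the 2 residual degrees of freedom leave little room for a call. Fry called retinoic acid response (adjusted p = 0.0432) and neurotransmitter systems (0.0473), both among the 7, and the Notch pathway (0.0152), which camera did not call. The other lists of the 7 had fry adjusted p between 0.0841 (cell cycle) and 0.0963 (neuron structure and ribosomal proteins). The whole course gave 8215 genes, 17766 probes on their own and 879 to 6628 without 1 array, the lowest without the differentiated vector array and 4509 without the undifferentiated vector array. Genes 2-fold apart in the undifferentiated, aggregated and differentiated states became 593, 482 and 684 with normexp, and 483, 361 and 480 at 3-fold. Of the values of named genes under the alternatives, 924 kept their call or value, 60 moved, 36 gained and 231 lost a call, and 0 turned in sign. These genes were picked for large differences, so a turn in sign was unlikely from the start. The cause of these changes was not tested, and leave-one-out fits assume that a lone array of a state varies like the others. Not run were normexp on mean signals, which the files lack, a fit to the authors' values, most of which are blank, and a slide block, which the state terms absorb for the lines and which is confounded with the undifferentiated state. The background filter leaves out genes seen on fewer than 2 arrays.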

Other observations

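Genes known to pattern the neural tube, some of them named in the report, were picked here after their values were seen, form no fixed list and have no test. In the differentiated state the ventral homeobox genes Nkx6-1 and Nkx6-2 were higher in the AICD line by 5.19 and 5.25, the motor neuron gene Isl1 by 2.78 and the Hedgehog receptor gene Ptch1 by 1.60, and Olig2 was at least 3.56-fold higher, while Foxa2, a gene of the floor plate and of endoderm, was at least 2.49-fold lower. The dorsal genes Pax3 and Zic1 had -2.97 and -1.96, Msx1 and Bmp4 had -2.23 and -2.33, and Pax7 was at least 2.18-fold lower. Olig3, which is dorsal in the spinal cord, had 2.35, and in the undifferentiated state Nkx6-1 had -0.26.

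The neurotransmitter list as a whole did not pass the test between the lines (median -0.08, camera adjusted p = 0.757, 0 of 26 members called by limma). In the differentiated state its median was -0.33 (-0.27 with genes at their bound, -0.17 with normexp correction), with 17 of 26 members lower (percentile 0.44 among random lists), and the members below are values chosen after they were seen. The inhibitory genes Slc32a1, Gad1 and Slc6a5 (vesicular transporter, GABA synthesis and glycine uptake) had -3.31, -2.88 and -3.91 in the differentiated state. For Slc32a1 the difference was already there, and larger, in the undifferentiated and aggregated states, as given above. The nicotinic receptor gene Chrna3 was at least 14.9-fold higher in aggregated AICD cells, and Ddc, which makes dopamine and serotonin, had 1.61 in the undifferentiated and 2.93 in the differentiated state. In the hypoxia and glycolysis list the glucose transporter genes Slc2a3 and Slc2a1 had 3.46 and 2.54 in the differentiated state, and Igf2, the ligand of Igf2r, had 1.78, -0.93 and -4.64.

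Of the tests below, the test of unchanged undifferentiated cells was written after the result was seen. The bootstrap intervals of the chromosome test and of the Notch test were added then too. All bootstrap intervals below resampled genes within the same arrays. They hold no spread between arrays or cultures and describe these arrays only. Genes that differ between the lines in all 3 states: the 10 splits of the 6 arrays into 3 and 3 are too few for a test, 1 of them, the real split, calling 47 genes and the highest other split 0. The gain or loss of 1 chromosome is argued against as the source of the 47 genes. They lay on 19 of 20 chromosomes with 5 on the fullest, and no chromosome kept a median difference beyond the bound of 0.3 in all 3 states. Chromosome 5 (827 genes) came nearest and was lower in the AICD line, with -0.25, -0.21 and -0.21 in the undifferentiated, aggregated and differentiated states. The smallest of these had a size of 0.208 (95% bootstrap interval over its genes 0.164 to 0.225). A loss in part of the cells, or of a chromosome segment, could stay below the bound and is not excluded. Whether AICD, the place where the construct entered the genome, or a difference between lines or clones accounts for the 47 genes stays open, since the line and all of these go together. More clones, or AICD switched on within 1 line, could part them.

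Pluripotency genes higher in the aggregated AICD cells: for Pou5f1 alone the scaling of arrays is argued against, since its difference was at least 5.09 under each of 3 other scalings, whereas the median of the list fell from 0.36 to 0.14 with normexp correction and its call over the 3 states ended (adjusted p = 0.253). Undifferentiated cells left in the AICD culture stay open. The test took 76 genes that fell at least 32-fold in the vector line. In the AICD line they kept a median of 8.49% of their undifferentiated level (95% bootstrap interval over genes 6.42 to 10.0), against 10.2% for Pou5f1. Their median of 1.95% in the vector line was fixed by that selection and is no contrast between the lines. Signals under the lowest signal well above background were set to it, so some shares are upper limits, such as 40.6% for Fam149a. Each share also compares arrays of different slides. Unchanged undifferentiated cells as the whole source of Pou5f1 are argued against, because 19 of 46 abundant genes kept less than 5.11%, the lowest being Cfc1 with 1.03%. A mixture with some undifferentiated cells, or cells that lose Pou5f1 more slowly, may each account for the rest; staining of Oct4 in single cells would part them.

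Hes5 and Dtx1 lower in the AICD line after aggregation: the 6 other Notch targets had a median of 0.10 (95% bootstrap interval over the 6 genes -1.33 to 0.96), from -2.58 for Hey2 to 1.37 for Hey1, with 3 of the 6 lower, and Hes7 was not well above background. The bound written before the data were examined was on the median alone and would have excluded lower Notch signalling as a whole; with the interval, which was added after the result was seen because the targets go both ways, it stays open. Neural progenitor genes went both ways. In the aggregated state they had a median of 0.04 and a mean of -0.31 (11 of 21 higher, 4 at least 2-fold higher and 5 at least 2-fold lower). In the differentiated state they had a median of 0.55 and a mean of 0.18 (13 of 21 higher, 8 at least 2-fold higher and 5 at least 2-fold lower). A change limited to Hes5 and Dtx1 would not cover Hey2, which had -2.58 and was well above background on both aggregated arrays. A reporter of Notch activity in both lines would test whether signalling differed.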
